A study of Mus musculus with 6 samples.

How the data were processed

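The samples were 6 RNA-seq libraries of female mouse neural progenitor cells from a hybrid of a CAST mother and a C57BL father, 3 labelled Control and 3 labelled MSL2KO1, grouped by the labels. All 6 sample titles also begin with CaBlCaXi, which was not used in reading the values. Per the labels' protocols, embryonic stem cells were differentiated into progenitors and Msl2 was disrupted with Cas9 and a pair of guide RNAs. Per the same protocols, single clones were genotyped. Per the submitters' processing notes, the authors named Trim Galore 0.6.5, STAR 2.7.4 and 2.7.9a, featureCounts 2.0.0, DESeq2 (without a version) and the mouse genome build mm10. The notes give no roles or order, and they also name tools of other assays. How reads were assigned to alleles, whether counting used strand and the library kit for RNA-seq are not given in the sources used here, so the value of a gene that overlaps a neighbour on either strand may include its reads. Besides those marked in the text, this applies to Msl1, Msl2, Atp5a1, Cnp, Col18a1, Fgfr3, Fkbp10, Gad1, H13, Hoxa5, Hoxa6, Mina, Mthfd2, Nap1l5, Ncald, Nnat, Nusap1, Pcdhgb4, S100b, Sox8, Sparcl1, Syn2, Tomm70a and Zbtb20, whose single values are uncertain to that extent.

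The files used hold the authors' own comparisons, with 1 row per gene for 47937 genes, and no values per library. In the total expression table and in the allelic table, the authors give a mean signal per gene, the mean of counts normalized for library size per the file headers. For the allelic comparison it is not stated whether this mean is per library or per allele. The log2 fold changes and their standard errors are the authors' values per the file headers. In the total table they were shrunk towards 0, since the fold divided by its standard error differs from the deposited statistic by up to 17.8, and no standard error exceeds 0.224. In the allelic table the fold divided by its standard error equals the statistic. The Wald statistic is deposited as a score per gene, and its normal tail gives the deposited p-value. Deposited p-values exist for 26267 genes in the total table and 22982 in the allelic table, and adjusted p-values for 17011 and 14160 of them, those with a mean normalized count of at least 5.14 and 3.27. The deposited text columns mark genes as up or down: in the total table the mark equals an adjusted p under 0.01 (1865 up and 1822 down), and in the allelic table it equals an unadjusted p under 0.05 with an absolute log2 value over 0.5 (875 genes, of which 360 have an adjusted p under 0.05), a rule that disagreed with the mark on 0 genes. The authors' classification lists 1897 genes with the same values, a class and a category, and writes a missing allelic adjusted p as 1 (32 genes). Missing adjusted p-values were left missing here.

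Depth per library is unknown, since the tables hold 1 mean per gene. The deposited standard error had a median of 0.0879 for called genes in total expression and 0.255 for called genes in allelic balance. For total expression it is the error of a shrunken fold, and fold over error differs from the deposited statistic by up to 17.8. A total value with its ± can therefore look firmer than its deposited Wald test, as for Csmd2 (5.20 ± 0.19, adjusted p = 2.8e-18). Because values per library were not used here, the deposited tests are the main results, and no count test, leave-out of a library, pairing or regrouping of samples could be run. Shrinkage makes total fold changes of low or variable genes smaller than unshrunk ones. The median total fold change of genes with a mean count of at least 100 was 0.0068 on the log2 scale, and the allelic median 0.0042.

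A gene was called at an adjusted p under 0.05. Gene positions and types come from GENCODE M21, which is on the same build, and 47310 of the gene identifiers had a position. Before the data were examined, 31 gene lists were fixed, with 695 distinct symbols (687 found and 572 with an adjusted p) and name patterns for gene families. Shifts of lists in total expression were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited statistic, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. This correlation cannot be estimated without values per library, so no call is known to hold with an estimated one. Allelic calls in lists, overlap of calls, chromosome shares and classes were tested with two-sided Fisher's exact tests (scipy 1.17.1, pandas 2.3.3, numpy 2.4.6, Python 3.11.15), adjusted over lists, pairs, chromosomes per direction or categories. Genes are not independent replicates in any of these tests.

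The chromosome scan was added after the values were seen. It used the 9777 genes with mean counts of at least 100 in the total table and 50 in the allelic table and an allelic standard error under 0.5, scored runs of genes against a shift of 0.5, and compared the highest score with 1000 permutations of gene order. Intervals of medians are from 10000 bootstrap draws over genes and so do not cover error shared by all genes of a library. On simulated values the scan recovered a run of 30 genes on a chromosome of 318 genes in 100 of 100 trials. The list test recovered 71 of 100 lists shifted by 3 on the statistic and called 0 of 400 unshifted ones, both over 17011 genes. The Fisher test recovered 100 of 100 sets of 200 genes called at double the background rate. Genes were drawn independently, so the 0 of 400 does not speak for lists whose genes vary together. Sets smaller than 200 genes, as most lists here, were not simulated for the Fisher test.

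Named genes follow a rule fixed before the data were examined: the MSL complex, the 12 largest rises and falls among called genes with a mean count of at least 100, the 10 largest allelic values in each direction among called genes with an allelic mean count of at least 20, up to 4 called members of smallest adjusted p per list, and the 6 genes of smallest p per class. Symbols made of Gm and digits, symbols ending in Rik and genes without a symbol were left out of the largest changes. Other genes in the text, among them the list members that did not pass, Xist, the genes of the chromosome 16 interval and the genes in the closing section, were chosen after their values were seen. Alternatives were stricter and looser thresholds, a fold minimum, other filters on low counts, recentring on the median gene with the deposited standard errors, protein-coding genes only, other settings of the list test, and, added after the values were seen, leaving out the chromosome 16 interval or the clustered protocadherins and requiring an adjusted p in the authors' classes. Plots were drawn with matplotlib 3.10.9.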

Results

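RNA was sequenced from female mouse neural progenitor cells, proliferating precursors of neurons and glia that had been differentiated from embryonic stem cells. The cells were hybrids with a CAST mother and a C57BL father, so that reads over sequence differences between the strains could be assigned to one of the 2 alleles of a gene. Control libraries (3) were compared with 3 libraries of cells in which Msl2 had been disrupted with Cas9, labelled MSL2KO1. MSL2 is the ubiquitin ligase subunit of the MSL complex, a histone acetyltransferase complex that acetylates histone H4. The study asked which genes change their total expression and which change the balance between their alleles when MSL2 is lost. The values used here are the authors' own comparison tables with 1 value per gene, so no value per library and no depth per library is known. Mean normalized counts summed to 53.8 M for total expression and to 9.91 M for reads assigned to an allele, where the mean may be per allele rather than per library. The allelic values rest on fewer reads, but these sums do not say by how much. The labels name 1 knockout and give no sign that the 3 replicates of a group came from separate clones or cultures. The p-values then measure the spread between these libraries, which may be technical.

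Total expression changed in both directions, mostly by small amounts, in the knockout cells. Proliferation genes rose together, while lists of neural progenitor, astrocyte and oligodendrocyte lineage markers and of clustered protocadherins shifted down, with members in each that did not change. The largest rises were those of Syt13, a synaptotagmin, at a log2 fold change of 6.02 ± 0.16 (standard error of the shrunken fold) in the authors' deposited table. Csmd2, a transmembrane protein with CUB and sushi domains, came next at 5.20 ± 0.19 in that table. Among genes with a mean count of at least 100, predicted genes named Gm or Rik left out, the largest falls in that deposited table were those of the potassium channel gene Kcnk1 at -3.90 ± 0.15 and the actin-binding protein gene Tagln2 at -3.41 ± 0.18. Of 17011 genes with an adjusted p, 5074 (29.8%) were below 0.05, with 2563 higher and 2511 lower in MSL2KO1, and 6617 genes had an unadjusted p under 0.05. An absolute log2 fold change of at least 1 was reached by 305 of them, 112 higher and 193 lower. Positive values are taken as higher in MSL2KO1, since the authors' class of genes named as down holds negative values only. The direction itself is not written in the tables.

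Msl2 itself (ENSMUSG00000066415, chromosome 9, positions 101074101 to 101104800, mm10) was not lower at the RNA level but was called slightly higher. Its log2 fold change in the authors' deposited table was 0.17 ± 0.07, with an adjusted p of 0.0352 that became 0.0540 when genes with low counts were kept in the adjustment. RNA of a gene cut by Cas9 need not fall, so this value does not check the labels. The other measured subunits of the complex did not pass the threshold. Kat8, the acetyltransferase, stood at 0.18 ± 0.08, Msl3 at 0.14 ± 0.06 and Msl1 at 0.08 ± 0.07 in the deposited table. Of the 9 genes of the NSL complex, which shares Kat8, 1 was called, Wdr5 at 0.26 ± 0.06. Neither list passed the list test (adjusted p = 0.302 for the MSL complex and 0.576 for the NSL complex). In the MSL complex 3 of 4 were higher adjusted over the list alone.

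Under the same limits the other genes with the largest rises were, in the authors' deposited table, Nol3 (4.50 ± 0.19), Klhl22 (3.95 ± 0.13), Parvb (3.50 ± 0.19), and the androgen receptor gene Ar (3.45 ± 0.20). They were followed in that table by the basement membrane collagen gene Col4a6 (3.35 ± 0.19), Eml2 (2.72 ± 0.20), Opcml (2.58 ± 0.10), the lysosomal glucuronidase gene Gusb (2.56 ± 0.10), the BMP and Wnt antagonist gene Sostdc1 (2.26 ± 0.15) and the small heat shock protein gene Hspb8 (2.08 ± 0.13). The other largest falls in the deposited table were those of Pcdhgb5 (-3.14 ± 0.11), Eya1 (-2.65 ± 0.15), Fndc3c1 (-2.56 ± 0.12), S100a16 (-2.19 ± 0.14), and Galk2 (-2.18 ± 0.11). Next in the deposited table came the thioredoxin-binding protein gene Txnip (-2.06 ± 0.12), Rgcc (-1.99 ± 0.11), the astrocyte water channel gene Aqp4 (-1.97 ± 0.16), Gpr37l1 (-1.96 ± 0.09) and Synpo (-1.95 ± 0.16). The largest adjusted p among these 24 genes was 2.8e-18, that of Csmd2. Nol3, Galk2 and Pcdhgb5 overlap other expressed genes, with which they may share reads.

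**Figure D1:**
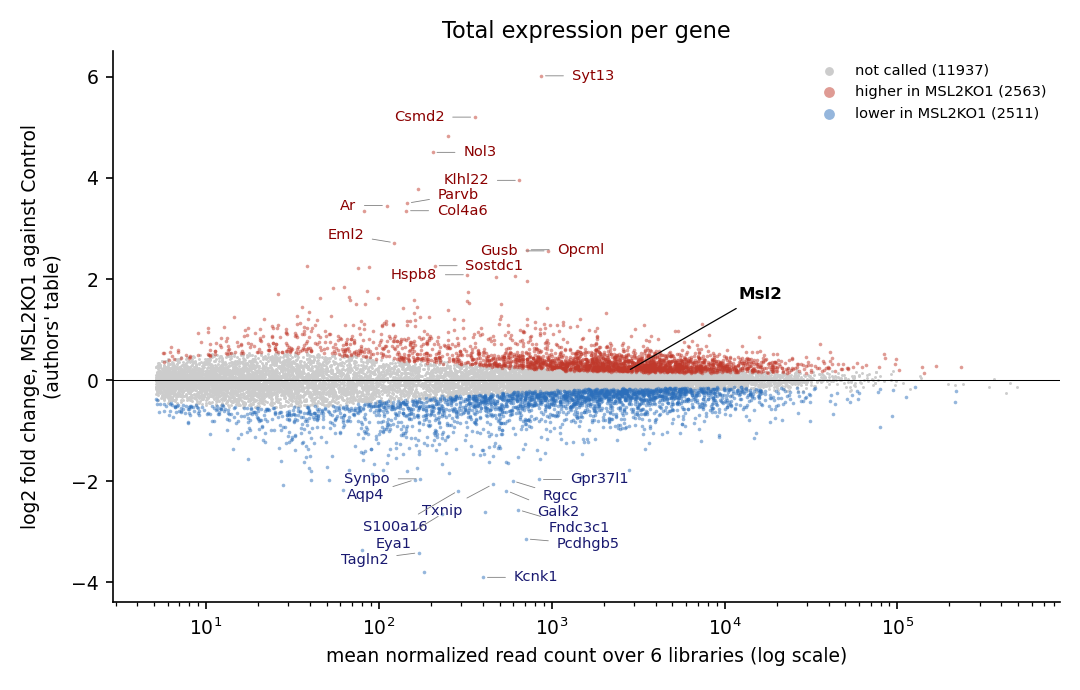
Log2 fold change of total expression between MSL2KO1 and Control against the mean normalized read count over the 6 libraries (log scale), 1 point per gene with an adjusted p in the authors' deposited table. Red points are the 2563 genes called higher, blue points the 2511 called lower, and the named genes are the 12 largest rises and the 12 largest falls under the limits on named genes, with Msl2 near 0.

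Cell cycle genes rose. Of 32 measured, 28 were higher and none lower (29 higher adjusted over the list alone), with a median log2 fold change of 0.39 and an adjusted p of 1.7e-16 in the list test. Among them, in the authors' deposited table, were the topoisomerase gene Top2a at 0.55 ± 0.06, the mitotic kinase gene Aurkb at 0.52 ± 0.06, the replicative helicase gene Mcm6 at 0.43 ± 0.05 and the spindle protein gene Nusap1 at 0.42 ± 0.06. Genes of the integrated stress response, induced through Atf4, shifted in the same direction. Of 20 measured, 9 rose and none fell (likewise adjusted over the list alone; median 0.13, adjusted p = 0.00198). The mitochondrial folate enzyme gene Mthfd2 stood at 0.87 ± 0.07, Chac1 at 1.34 ± 0.22, Shmt2 at 0.42 ± 0.06 and the asparagine synthetase gene Asns at 0.43 ± 0.07 in the deposited table. Cytosolic ribosomal protein genes had a median of 0.02, with 1 of 85 higher and 1 lower.

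Neural progenitor markers fell on balance. Of 26 measured, 13 were lower and 3 higher (14 and 4 adjusted over the list alone; median -0.22, adjusted p = 5.5e-05). The Notch effector gene Hes5 stood at -2.17 ± 0.21, and the SOXB1 factor genes Sox1 and Sox3 at -1.44 ± 0.14 and -1.25 ± 0.09 in the authors' deposited table, with Olig2 at -0.68 ± 0.07. Not all members moved that way. In the same deposited table the intermediate filament gene Nes was higher at 0.26 ± 0.07, and Vim at 0.06 ± 0.06 and Pax6 at -0.11 ± 0.08 did not pass. Astrocyte markers showed the largest median among the marker lists. Of these, 9 of 14 were lower and none higher (9 and 1 adjusted over the list alone; median -0.50, adjusted p = 7.1e-06). Besides Aqp4, the deposited table gave S100b at -1.13 ± 0.10, the growth factor receptor gene Fgfr3 at -0.92 ± 0.08 and Mlc1 at -0.34 ± 0.05. The abundant markers Apoe (-0.08 ± 0.09), Sparcl1 (0.10 ± 0.05), Aldoc (0.06 ± 0.07) and Gja1 (0.11 ± 0.05) did not pass in that table. Of 11 oligodendrocyte lineage markers, 5 were lower and 1 higher, likewise over the list alone (median -0.35, adjusted p = 0.00105). The precursor genes Olig1 at -0.71 ± 0.06, Sox8 at -0.57 ± 0.07 and Pdgfra at -1.05 ± 0.17, and the myelin enzyme gene Cnp at -0.71 ± 0.08, were among them in the deposited table. Olig2 is a member of both the progenitor and the oligodendrocyte lists. Neuron markers went both ways, with 4 higher and 5 lower of 24 (adjusted p = 0.290). The growth cone protein gene Gap43 stood at -1.16 ± 0.09, Gad1 at -0.73 ± 0.13 and Elavl4 at 0.64 ± 0.13 in the deposited table.

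Clustered protocadherins, cell surface adhesion molecules encoded in 3 neighbouring arrays on chromosome 18, shifted down as lists, the gamma array least firmly. In the alpha array 8 of 13 genes were lower and none higher, also over the list alone (median -0.57, adjusted p = 0.00390). The beta array had 10 of 21 lower and 4 higher (13 and 4 adjusted over the list alone; median -0.39, adjusted p = 0.00159). The deposited table gave Pcdhb4 at -1.44 ± 0.12, Pcdhb10 at -1.39 ± 0.11 and, in the other direction, Pcdhb6 at 0.66 ± 0.09. In the gamma array 6 of 22 were lower and 2 higher (6 and 3 adjusted over the list alone; median -0.15, adjusted p = 0.00954). The deposited table held both the fall of Pcdhgb5 and a rise of Pcdhgb4 to 1.59 ± 0.21. The gamma shift did not pass at a preset correlation of 0.05 (adjusted p = 0.0832) or on ranks (adjusted p = 0.286). Among 10000 random lists matched on mean expression, the gamma median stood at percentile 6.95. Members of the alpha and gamma arrays share their 3′ exons, so reads of a member can be split among its neighbours and single values are uncertain. Non-clustered protocadherins did not pass the list test (1 higher and 1 lower of 10, median 0.11 against a mean statistic of -1.15, adjusted p = 0.466). Single members changed, however: Pcdh10 was among the genes with the smallest p at -1.78 ± 0.09 and Pcdh17 was higher at 0.75 ± 0.12 in the deposited table.

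The list of zinc finger genes of the Zfp family shifted down by a small amount (median -0.13, adjusted p = 0.00159, but 0.222 at a preset correlation of 0.05). Of 311 measured, 88 were lower, 15 higher and 208 not called (91 and 18 adjusted over the list alone). Zfp13 at -1.46 ± 0.14 and Zfp811 at -1.19 ± 0.14 fell most clearly, and Zfp692 was higher at 0.94 ± 0.09 in the authors' deposited table. Interferon response genes had 8 of 20 lower and 1 higher (9 and 2 adjusted over the list alone; median -0.22, adjusted p = 0.0209). Among them were Rsad2 at -0.84 ± 0.13, Ifitm3 at -0.78 ± 0.10 and the class I antigen gene H2-K1 at -0.54 ± 0.10 in the deposited table. Oxidative phosphorylation subunits had 8 of 77 lower and none higher (7 lower adjusted over the list alone; median -0.13, adjusted p = 0.0208). Members included Atp5a1 at -0.36 ± 0.05 and the testis-type subunit gene Cox6b2 at -1.54 ± 0.17 in the deposited table. The last 2 shifts also did not pass at a preset correlation of 0.05, where the adjusted p was 0.126 for the interferon list and 0.283 for the oxidative phosphorylation list.

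The remaining lists did not pass the list test. By percentile among the random lists matched on expression, the Wnt, Notch, Shh and BMP median stood at 0.35 and the matrix median at 0.49. That of mesenchymal and neural crest markers stood at 98.98 and that of Polycomb and DNA methylation genes at 99.69. The others of these lists lay between 2.08 (X inactivation centre) and 84.26 (genes escaping X inactivation). Wnt, Notch, Shh and BMP pathway genes (9 higher and 19 lower of 52, adjusted p = 0.0718) held falls of Dll3 to -1.16 ± 0.09, Wnt7a to -0.93 ± 0.08 and Wnt5a to -0.77 ± 0.07 and a rise of Fzd10 to 1.03 ± 0.10 in the authors' deposited table. Extracellular matrix genes (11 higher and 14 lower of 44, adjusted p = 0.246) went both ways, with Thbs1 at 1.20 ± 0.10 and Itgb8 at -1.05 ± 0.09 in the deposited table. Axon guidance and adhesion genes (16 higher and 20 lower of 58, adjusted p = 0.576) had a positive median of 0.03 and a negative mean statistic of -0.454. The 25 p53 targets (7 higher and 5 lower, adjusted p = 0.794) likewise had a median of 0.05 and a mean statistic of -0.219. Among those targets, Btg2 stood at -1.03 ± 0.06, Sesn1 at -0.76 ± 0.07 and Aen at 0.51 ± 0.06 in the deposited table. Polycomb and DNA methylation genes had 9 of 25 higher and 3 lower (adjusted p = 0.221), and Hox genes 4 of 18 higher and none lower (0.471). Neurodevelopmental disorder genes had 16 of 96 higher and 17 lower (0.647), and regional patterning factors 7 of 28 higher and 5 lower (0.736). Imprinted genes had 9 of 43 higher and 11 lower (adjusted p = 0.736), with Nap1l5 at -0.60 ± 0.06 and Nnat at 0.50 ± 0.07 in the deposited table. Genes of the X inactivation centre had 3 of 7 lower and none higher (adjusted p = 0.221), Xist itself standing at -0.06 ± 0.10 in the deposited table. Genes escaping X inactivation had 4 higher and 4 lower of 18 (adjusted p = 0.736). No list of markers of other cell types passed. Of 24 pluripotency markers 8 were measured (3 higher and 2 lower, adjusted p = 0.619). Of 22 mesoderm and endoderm markers 8 were measured (1 and 1, 0.794). Of 24 mesenchymal and neural crest markers 18 were measured (5 and 3, 0.576). Olfactory receptors had 2 higher and 2 lower of 6 (0.673). The ribosomal list also did not pass (adjusted p = 0.738). Adjusted over the list alone, the calls in these lists were the same except in the Wnt group (12 higher and 19 lower), axon guidance (20 and 21), Polycomb (10 and 3), disorder genes (16 and 19), imprinted genes (10 and 13), the X inactivation centre (0 and 4) and mesoderm and endoderm (1 and 2).

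**Figure D2:**
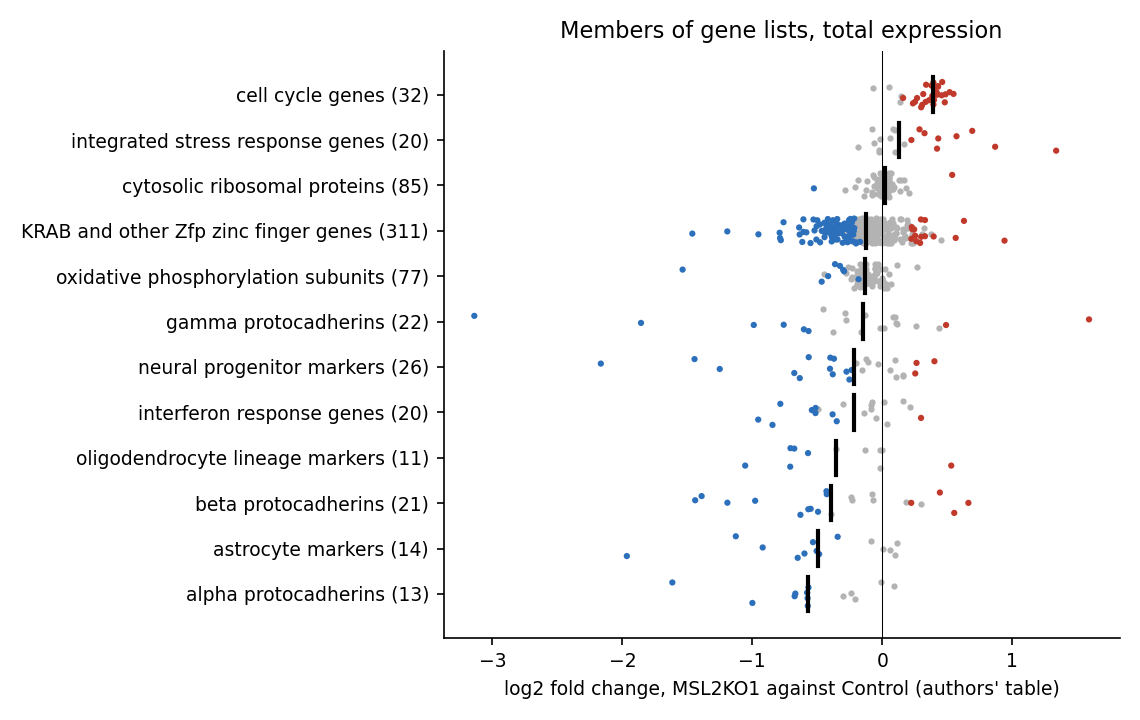
Log2 fold change of total expression for each measured member of the 11 gene lists that shifted and of the cytosolic ribosomal protein genes, from the authors' deposited table, with the number of members in brackets. Red and blue points are members called higher and lower, grey points were not called, vertical bars are medians, and vertical scatter within a row is random. The median is 0.39 for cell cycle genes, 0.02 for ribosomal proteins and -0.50 for astrocyte markers.

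The balance between alleles changed in a smaller set of genes. In the allelic table, which compares the ratio of allele 2 to allele 1 between the groups, 401 of 14160 genes (2.83%) had an adjusted p under 0.05. Of these, 169 shifted towards allele 2 (positive values) and 232 towards allele 1 (negative values), and 147 had an absolute value of at least 2 on the log2 scale. The orientation rests on the names of the authors' biallelic classes alone (bias towards allele 1 holds negative values only, bias towards allele 2 positive ones). The monoallelic classes have the opposite signs, and the tables do not say which strain is allele 1. Among called genes with an allelic mean count of at least 20, and leaving out predicted genes named Gm or Rik, the largest shifts towards allele 2 in the authors' deposited table were those of Hspb8 (13.002 ± 1.338), the translation factor gene Eif2d (8.84 ± 0.84), B9d1 (8.10 ± 2.01), and Kcnk1 (7.33 ± 1.22). Then came Parvb (7.28 ± 1.03), the X-linked Atp6ap2 (7.18 ± 0.34), Eml2 (7.18 ± 1.46), Pdzrn4 (6.96 ± 0.63), Zfp583 (6.31 ± 1.27) and Mmp11 (5.80 ± 1.10) in that table. Under the same limits the largest towards allele 1 in the deposited table were those of AA474331 (-15.04 ± 1.41), the adhesion molecule gene Sdk2 (-9.43 ± 1.26), and Csmd2 (-8.82 ± 1.81). Then came Syt13 (-7.11 ± 0.82), Layn (-6.78 ± 1.05), Nudt16 (-6.74 ± 1.23), the mitochondrial reductase gene Decr1 (-6.12 ± 0.62), the X-linked Snx12 (-6.12 ± 0.49), Cers4 (-6.09 ± 1.31) and Acsl5 (-5.80 ± 1.23) in that table. Values of this size need an allele with very few reads in one of the groups, and the counts per allele are not in the tables, so they give a direction more than a size. Eif2d and Acsl5 overlap other expressed genes.

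Among the fixed lists, the beta protocadherins held more allelic calls than other genes: 5 of 21 tested (23.8%) against 2.80% elsewhere (12 called adjusted over the list alone; Fisher's exact test, odds ratio 10.8, adjusted p = 0.00770). Pcdhb4 at -1.72 ± 0.23, Pcdhb19 at -1.45 ± 0.16 and Pcdhb9 at -1.19 ± 0.20 shifted towards allele 1, and Pcdhb6 at 0.98 ± 0.18 towards allele 2 in the authors' deposited table. Astrocyte markers (3 of 14), mesenchymal and neural crest markers (3 of 12) and extracellular matrix genes (5 of 44) each had an adjusted p of 0.0603, and each was at 0.0406 once the chromosome 16 interval described below was left out. The 3 astrocyte markers were Sparcl1 (-1.003 ± 0.053), Apoe (-0.73 ± 0.19) and Aldoc (-0.41 ± 0.12), all towards allele 1 in the deposited table, and none of them changed in total expression. The matrix genes included Nid1 (3.05 ± 0.30), Col18a1 (1.08 ± 0.16) and Itga7 (-4.39 ± 0.62) in the deposited table. Of the MSL genes, Msl3, which lies on the X chromosome, shifted towards allele 2 by 2.20 ± 0.32, while Msl2 stood at -0.09 ± 0.17 in the deposited table. Imprinted genes held 1 call among 42 tested, H13 at -0.58 ± 0.15 in the deposited table. Of the 38 with a total mean count of at least 100, 8 had an allelic standard error over 1, too large for most shifts to be called. Neural progenitor markers (23), cell cycle genes (31), ribosomal proteins (76) and oxidative phosphorylation subunits (72) held none. In all, 1190 genes had an unadjusted p under 0.05. Among the other lists with calls were the Wnt, Notch, Shh and BMP genes (4 of 45, Sfrp1 at -2.65 ± 0.46) and the axon guidance genes (3 of 55, Sema3d at 3.68 ± 0.67). The Zfp genes held 10 of 292 and the Hox genes 2 of 18 (Hoxa5 at 1.00 ± 0.21 and Hoxa6 at 2.74 ± 0.42), values from the deposited table. Gamma protocadherins held 2 of 21, regional patterning factors 2 of 24 and disorder genes 2 of 91. The neuron, oligodendrocyte, interferon, integrated stress response, X escape and olfactory receptor lists held 1 each. None of these lists passed the test.

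Changes of allelic balance and of total expression fell on the same genes more often than independent calls would. Over the 14160 genes tested in both tables, 284 of the 401 allelic calls (70.8%) also changed in total expression, where 136 were expected for independent lists (Fisher's exact test, odds ratio 4.97, adjusted p = 6.8e-52). The overlap was 176 genes for lower total expression (expected 66.8, odds ratio 4.15) and 108 for higher (expected 69.0, odds ratio 1.81). Both tables come from the same libraries and genes are not independent replicates, so the p describes these calls only. Total expression also holds the reads of both alleles, so a change in 1 allele alone moves both values. Some excess over independent calls is therefore built in. Total changes of at least 1 on the log2 scale carried an allelic call in 28 of 106 genes that were higher (26.4%, 95% Clopper-Pearson interval 18.3% to 35.9%) and in 40 of 181 that were lower (22.1%, 16.3% to 28.9%), against 3.43% and 6.25% of the genes with smaller changes. These bins were chosen after the values were seen. The direction of the allelic shift did not follow from the direction of the total change. Syt13 rose with a shift towards allele 1 and Opcml (3.15 ± 0.36) with a shift towards allele 2. Kcnk1 fell with a shift towards allele 2 and Galk2 (-3.01 ± 0.42) and Tagln2 (-4.06 ± 1.09) with a shift towards allele 1, all in the authors' deposited tables.

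**Figure D3:**
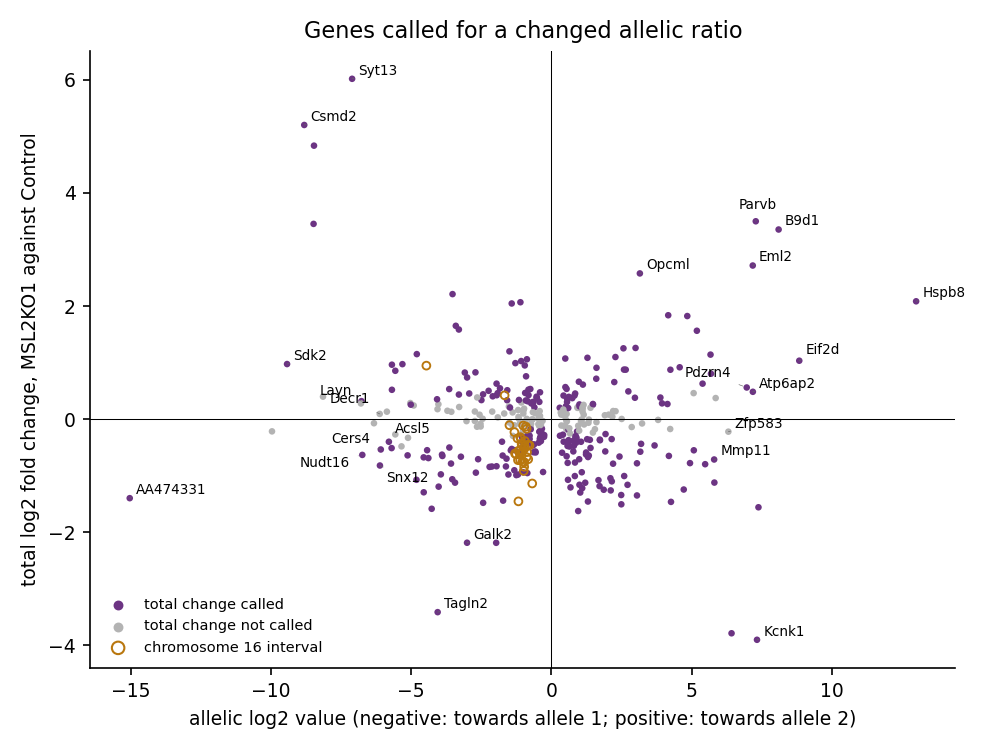
Total log2 fold change against the allelic log2 value for the 401 genes with an allelic adjusted p under 0.05, from the authors' deposited tables. Purple points also changed in total expression, grey points did not, and open circles are the 38 called genes of the chromosome 16 interval, which cluster near an allelic value of -1.

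Along the chromosomes, lower genes were commoner on chromosomes 16, 18 and X. On chromosome 16, 119 of 501 genes (23.8%) were lower against 14.6% elsewhere (Fisher's exact test, odds ratio 1.83, adjusted p = 1.8e-06). The counts were, on chromosome 18, 98 of 467 (odds ratio 1.55, adjusted p = 0.00269), and on the X chromosome, 120 of 628 (19.1% against 14.7%, odds ratio 1.38, adjusted p = 0.0191). Of the 98 lower genes on chromosome 18, 24 were clustered protocadherins, and without that family, a comparison added after the values were seen, the odds ratio was 1.28 (adjusted p = 0.266). The X chromosome also held fewer higher genes, 68 of 628 (10.8% against 15.3%, adjusted p = 0.0229), although this did not pass at an adjusted p under 0.01 for the calls or among genes with a mean count of at least 100 (adjusted p = 0.0845 and 0.0509). Higher genes were commoner on chromosomes 8, 10, 15 and 17 (18.3% to 19.5%) and rarer on chromosomes 1 and 3 (12.6% and 12.4%), with adjusted p between 0.0229 and 0.0484. None of these 6 passed among genes with a mean count of at least 100 (adjusted p between 0.0874 and 0.387), and with calls at an adjusted p under 0.01 only chromosomes 3 and 15 did. Allelic shifts towards allele 1 were concentrated on chromosome 16, with 42 of 431 genes (9.74%) against 1.39% elsewhere (odds ratio 7.66, adjusted p = 1.1e-19), and no other chromosome passed in either direction.

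Of the 42 shifts towards allele 1 on chromosome 16, 38 lay in 1 interval of 15.9 Mb (positions 42875881 to 58734251, mm10, from Zbtb20 to Cldnd1), found by a scan of allelic values along gene order. Of the 119 lower genes of the chromosome, 43 lay in it and 76 outside. All 40 genes with enough reads for the scan had negative allelic values there, with a median of -1.04 (95% bootstrap interval -1.10 to -0.97), and their median total log2 fold change was -0.56 (-0.61 to -0.45). The other 278 scanned genes of the chromosome had medians of 0.01 in both tables. The interval scored 21.7, where the highest score among 1000 permutations of the gene order was 3.12 (p = 0.001, the smallest they can give). Of all genes in it, 38 of 56 tested shifted towards allele 1 and none towards allele 2, and 43 of 66 were lower and 3 higher in total expression. The named genes, chosen after their values were seen, include Atp6v1a (allelic -0.99 ± 0.09, total -0.76 ± 0.06), Naa50 (-1.04 ± 0.10 and -0.45 ± 0.07), Pvrl3 (-1.02 ± 0.10 and -0.57 ± 0.06) and Tomm70a (-0.96 ± 0.10 and -0.47 ± 0.06) in the authors' deposited tables. Higher total values occurred for Ccdc80 (0.95 ± 0.13, allelic -4.46 ± 0.48) and Alcam (0.42 ± 0.11, allelic -1.67 ± 0.31) in these tables. The nearest scanned genes outside had allelic values of 2.71 ± 0.36 (Gap43) and -0.16 ± 0.17 (Mina) in the authors' table. Without the genes of the interval the allelic calls numbered 363, with 194 towards allele 1, and chromosome 16 no longer differed from the others in lower genes (odds ratio 1.24, adjusted p = 0.329). Of the fixed lists, the pluripotency and ribosomal lists alone have measured members there, such as Rpl24 at -0.53 ± 0.14 and Dppa2 at -0.80 ± 0.21 in total expression in the deposited table, and all 11 list shifts passed without it.

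**Figure D4:**
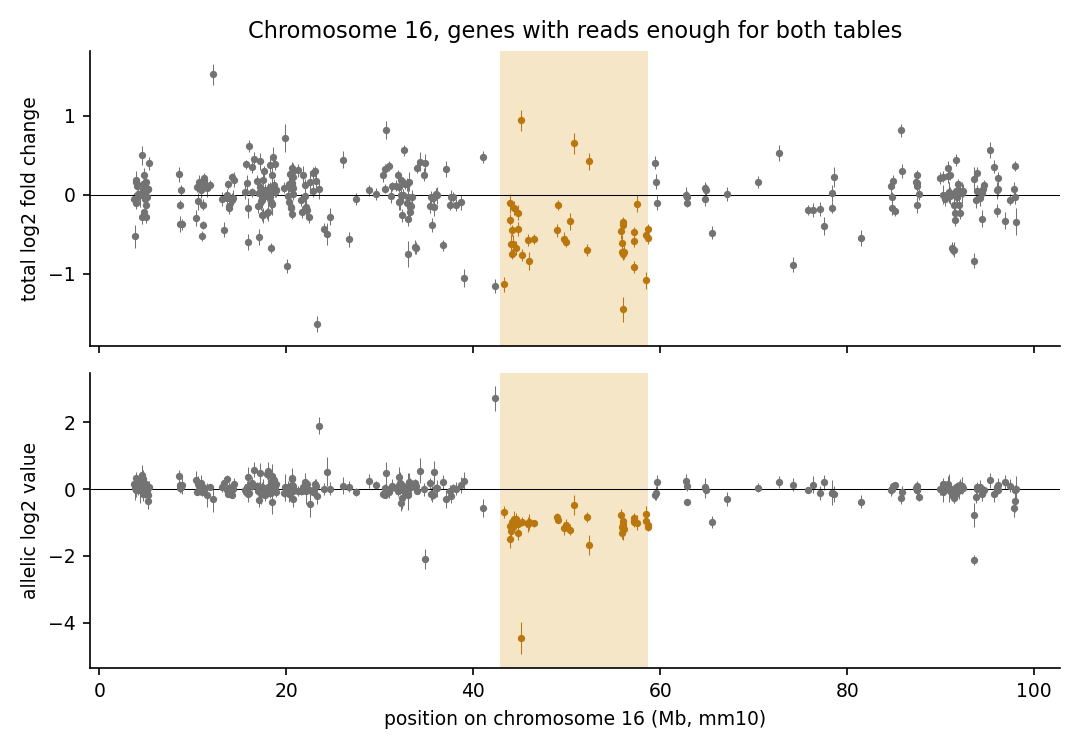
Total log2 fold change (top) and allelic log2 value (bottom) of the scanned genes of chromosome 16 by position (Mb, mm10), with error bars of 1 standard error, from the authors' deposited tables. The shaded span is the interval of 15.9 Mb, in which all 40 genes have allelic values below 0 with a median of -1.04.

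The authors sorted 1897 genes into classes, by a rule that the deposited tables do not give. Most, 1323, were lower in total expression without the authors' allelic mark, and 574 were allele-biased. These are 173 and 177 genes named as expressed from both alleles and biased towards allele 1 or allele 2, and 105 and 119 genes named as monoallelic for allele 1 or allele 2. How a gene was called monoallelic is not given either. The class lower on both alleles had a median total log2 fold change of -0.48. The smallest p in it were those of Gpr37l1, Pcdhgb5, Fndc3c1, Pcdh10, the calcium sensor gene Ncald (-1.08 ± 0.06) and the synapsin gene Syn2 (-1.37 ± 0.07) in the authors' deposited table. In the class lower on both alleles, lack of the mark does not show an equal fall where the allelic standard error is large. Fndc3c1 is such a gene (allelic 2.71 ± 1.69). The 4 biased classes had medians between -0.34 and -0.19. Genes with the smallest allelic p included Rbfa (-5.70 ± 0.33), Renbp (-4.56 ± 0.28) and the amino acid transporter gene Slc38a1 (-2.21 ± 0.15) in the class biased towards allele 1. The class biased towards allele 2 included Megf6 (3.05 ± 0.15), Grid1 (3.80 ± 0.23) and Arsb (1.33 ± 0.12) in the deposited table. Among monoallelic genes, Pdzrn4, Fkbp10 (5.67 ± 0.31) and Mlh3 (3.94 ± 0.30) of allele 1 had positive values and Fam73a (-5.02 ± 0.22), Ifitm3 (-3.58 ± 0.23) and Slc12a7 (-1.91 ± 0.18) of allele 2 negative ones in the deposited table. With the orientation taken from the biallelic names, that is away from the allele they are named for.

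All biased genes carried the authors' allelic mark, which equals an unadjusted p under 0.05 with an absolute log2 value over 0.5. An adjusted p under 0.05 was met by 263 of the 574 (90 and 68 of the biallelic classes biased towards allele 1 and allele 2, 46 and 59 of the monoallelic classes). The classification left out 301 genes with the authors' allelic mark, whose median total log2 fold change was 0.26 against -0.30 for the 574 classified. The classification therefore leans towards genes that were lower and its direction is not independent evidence of one. The chromosome 16 interval supplied 27 of the 173 genes biased towards allele 1 (15.6%) and 15 of the 119 monoallelic genes of allele 2 (12.6%), none of the 2 classes with positive values and 4 of the 1323 lower on both alleles. Within the classification, by the authors' categories, random monoallelic genes were allele-biased more often than the rest (94 of 175, 53.7%, against 27.9%). The odds ratio was 3.00 (Fisher's exact test, adjusted p = 5.7e-11). Protocadherins were too (15 of 27, odds ratio 2.93, adjusted p = 0.00973). All other classified genes are of the class lower on both alleles. The shares by category therefore set biased genes against lower ones and are not rates among all genes of a category. Genes subject to X inactivation carried the mark less often (8 of 58, 13.8%, odds ratio 0.360, adjusted p = 0.00973). Their allelic standard errors are large, however (median 1.39 over the 56 tested with a total mean count of at least 100, against 0.18 over all such genes), so a shift could hardly have been called in most of them and the low share does not show that they shifted less. Imprinted genes (8 of 19, adjusted p = 0.393) and genes escaping X inactivation (5 of 20, adjusted p = 0.807) did not differ detectably.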

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

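Leaving out the chromosome 16 interval or the clustered protocadherins, other scan settings and requiring an adjusted p in the authors' classes were chosen after the values were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because the deposited tables hold 1 value per gene for the whole comparison and none per library, and for the same reason no library could be left out in turn. Depth per library is unknown, and the shrunken total fold changes limit what can be said about the size of changes in genes with low counts. With stricter and looser thresholds, other filters, recentring on the median gene, protein-coding genes only or without the interval, the counts of total calls ranged from 3687 to 6034 and of allelic calls from 302 to 488, all within 1.5 times the reported 5074 and 401. A fold minimum of 1 left 305 total calls (112 positive, 193 negative) and 260 allelic calls (108 positive, 152 negative), because it removes small changes by construction. The overlap of total and allelic calls kept its direction and its side of the threshold at every alternative run, with odds ratios from 4.46 to 5.84 for any change.

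Of the 11 list shifts, 7 passed at a preset correlation of 0.05, 10 on ranks, 10 among genes with a mean count of at least 100 (interferon list, adjusted p = 0.0527) and 11 without the interval. Allelic calls were enriched in 4 lists at an adjusted p under 0.1 and in 4 without the interval, against 1 as reported; the second change comes from the lower background rate, since the calls in those lists were the same genes. Chromosome shares passed in 6 cases with calls at an adjusted p under 0.01, in 6 with a mean count of at least 100 and in 9 without the interval, against 11. With the higher count minimum 4 of the 11 were kept, 7 were lost and 2 others passed (fewer lower genes on chromosome 8, adjusted p = 0.0281, and fewer negative allelic values on chromosome 4, adjusted p = 0.0209); the cause was not tested. Without the interval, the odds ratio of chromosome 16 was 1.24 for lower total expression (adjusted p = 0.329) and turned from 7.66 to 0.765 for negative allelic values (adjusted p = 0.865). That of chromosome 18 for lower total expression was 1.28 without the clustered protocadherins. That of chromosome X for higher total expression was 0.724 at the stricter threshold and 0.661 with the higher count minimum, neither past the threshold; the cause was not tested. Of the 574 allele-biased genes, 263 had an adjusted p under 0.05. The interval's medians stayed within their bootstrap intervals with other scan settings (total -0.56, allelic -1.04 in each). Of the 195 genes named in the text or its tables that were called in total expression, 5 lost the call with no filter on low counts, Msl2 among them, 1 after recentring and 15 at 0.01. Of the 90 called in the allelic table, 1 (Tfap2a) lost the call with no filter and 4 at 0.01. No named gene that was called changed its sign.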

Other observations

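The gene list shifts cited in this part were planned; the scan along the chromosomes, the selection of X-linked genes and the tests of explanations were chosen after the results were seen. On the X chromosome, 17 genes changed their allelic ratio, 11 towards allele 1 and 6 towards allele 2, and 10 of them by at least 2 on the log2 scale. In the authors' deposited tables the shift of Atp6ap2, an accessory subunit of the proton pump, towards allele 2 (7.18 ± 0.34) came with a rise in total expression of 0.48 ± 0.07, and that of Msl3 (2.20 ± 0.32) without a detectable one (0.14 ± 0.06). The neighbours Snx12 (-6.12 ± 0.49) and Foxo4 (-3.90 ± 0.45) both shifted towards allele 1 and both fell, by 0.82 and 0.63 in the deposited table, and Renbp (-4.56 ± 0.28) fell by 0.67. Ar rose by 3.45 ± 0.20 and was called towards allele 1 on few reads (allelic mean count 15.1), so the size of that shift is uncertain. Xist, which coats the inactive X chromosome, did not change its allelic ratio detectably (0.21 ± 0.18, adjusted p = 0.9994 in the deposited allelic test). The 7 X-linked genes that the authors call monoallelic are all named for allele 1. Which X chromosome was inactive was not examined, and the CaBlCaXi of the sample titles was not used to orient the alleles.

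A second, much shorter run of neighbours lies on chromosome 9 (positions 108565537 to 108597667, mm10), with a score of 2.41 (permutation test over the genome, p = 0.015). In the authors' deposited tables Ndufaf3 (-1.74 ± 0.25), Dalrd3 (-1.29 ± 0.31) and P4htm (-2.62 ± 0.34) shifted towards allele 1 there, while Wdr6 between them, the most abundant of the 4, stood at -0.12 ± 0.10. Their total expression went apart: Ndufaf3 and P4htm stood at -0.64 ± 0.12 and -0.71 ± 0.12 and Dalrd3 at 0.99 ± 0.10. Dalrd3 and Wdr6 overlap, so that their reads may be shared; the score of 2.41 does not separate that from a change in the region.

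Lower total expression and a shift towards allele 1 ran together over 15.9 Mb of chromosome 16. Genes that changed on their own are argued against by the score of 21.7, since the highest of 1000 permuted gene orders was 3.12. A loss of 1 of 2 copies in 0.5 of the cells would give a total value of -0.42, above the upper end of the bootstrap interval at -0.45. Other fractions were not tried, and the interval leaves out error shared by all genes of a library. A loss in some other part of the cells therefore stays open. A candidate explanation is a difference in copy number, 3 copies in Control and 2 in MSL2KO1, with 1 allele doubled in Control. It predicts -0.58 for total expression and -1 for the allelic value. The medians of -0.56 and -1.04 have intervals that hold both, but the explanation was built from these values and no DNA was examined. The predicted totals of -0.58 and -0.42 are not shrunk, while the observed total folds were shrunk towards 0. Unshrunk folds could therefore lie further from 0. The doubled allele would be allele 2 under the orientation taken from the biallelic names, and allele 1 if that were turned; if the total direction were turned, the extra copy would lie in MSL2KO1. A regional effect of losing MSL2 cannot be told apart from it, since the samples hold 1 knockout clone.

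The list of cell cycle genes shifted up, while the lists of progenitor, astrocyte and oligodendrocyte lineage markers shifted down, with 13 of 26, 9 of 14 and 5 of 11 members called lower. A scaling error between the groups is argued against by the ribosomal protein genes, whose median of 0.0184 (upper quartile 0.05) lies far below the cell cycle median of 0.39. A smaller share of astrocyte-like cells in the knockout cultures may contribute: 64.3% of the measured astrocyte markers were lower, but the others, among them Apoe and Sparcl1, are also made by progenitors, whose high level could hide a small loss, so it cannot be told apart from a change within progenitors. Whether the loss of MSL2 rather than another property of the clone lies behind the shift cannot be told apart either, with 1 knockout clone among the samples.

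The authors' allele-biased classes mix genes with different support. Chance as the only source of the allelic marks is argued against by 241 genes with a p under 1 over the number of genes, among all 22982 with an allelic p, where chance gives 1. The share with an unadjusted p under 0.05 was 5.18% of these 22982 (1190 genes, 95% Clopper-Pearson interval 4.90% to 5.47%). Of these 1190, 1127 were among the 14160 genes kept for the adjustment, 7.96% of them. The genes left out of the adjustment therefore held few small p-values, so the 5.18% cannot be set against a chance rate of 5%. How many of the 311 biased genes past the unadjusted threshold alone are chance was not tested. Among well-expressed genes past the adjusted threshold, random monoallelic genes were commoner than in the class lower on both alleles. Of such genes in this comparison 36 of 102 were biased, against 191 of 1330 others (odds ratio 3.25, p = 6.6e-07, Fisher's exact test). The comparison class holds only genes with lower total expression, so these are not rates among all genes of the category. Clonal random monoallelic expression, in which single clones differ in the allele they use, could give such an excess. A low share of these genes in the comparison class could give it too. The odds ratio was 3.89 without the chromosome 16 interval. An effect of losing MSL2 on the same genes stays open and was not tested, because a second knockout clone is not among the samples.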
